A study of Nematostella vectensis with 9 samples.

How the data were processed

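Total RNA was measured in whole embryos of the starlet sea anemone Nematostella vectensis, an anthozoan cnidarian used to study early animal development. Per the labels' protocols, fertilized and injected eggs were raised at 17 °C in diluted seawater, about 1 µg of total RNA per sample was enriched for poly-A mRNA, and single-end libraries of 50 bp reads were made. Each of the 9 samples was collected at 24 h after fertilization. The groups were embryos injected with a morpholino (a synthetic antisense oligonucleotide that blocks translation or splicing of its target) against NvBMP2/4, embryos injected with RNA for a dominant negative form of NvTCF, and control embryos injected with dextran, with 3 samples in each. The series' design text calls the samples of a group biological replicates.

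The deposited values were raw read counts per reference sequence, 1 table per library, and per the submitters' processing notes the tools FastQC and Bowtie2 2.2.0 were used. Per the row names in the files, the reference held JGI Nemve1 gene models together with an 18S rRNA, a 28S rRNA and a mitochondrial sequence. The counting program, the filters, the strand setting and the treatment of reads that match several models are not given in the sources used here, so models with near-identical copies may share reads. A sequence with no count was absent from a library's table (the lowest listed count was 1), and it was entered as 0. The row marked with an asterisk, which names no sequence and was taken to hold the reads without an assigned reference, was left out of library sizes and tests. It held 39.6% to 87.8% of a library's counts. The 18S, 28S and mitochondrial rows were also left out of the main test and are reported separately. No 2 libraries held identical counts, and the closest pair correlated at r = 0.96 on the log2 scale.

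The files gave model numbers without gene names or coordinates. None of the 21946 model numbers matched the RefSeq gene table of assembly jaNemVect1.1, in which 38762 rows were searched by locus tag, older locus tag, synonym and symbol. Gene names were not assigned. The 19 gene lists fixed in advance (BMP, Wnt, FGF, Notch and Hedgehog signalling, endomesoderm, oral, aboral, Hox and directive axis, neural, cnidocyte, gland, muscle, germ line, RNA sensing, stress, cell cycle, ribosomal protein and matrix genes) were defined by gene names and were therefore not tested. The levels of the targeted genes were likewise not analysed here, so the knockdown and the injected RNA were not checked in these counts.

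Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, and the quasi-likelihood F-test (glmQLFit, glmQLFTest) on all 9 libraries with 1 mean per group, so that 6 residual degrees of freedom set the spread. P-values were adjusted by the Benjamini-Hochberg method, and a model was called at an adjusted p under 0.05 with no fold threshold. Standard errors of log2 fold changes were derived from the F statistic. Levels are given as TMM-scaled CPM (counts scaled to a library total of 1e6), mean ± SD over 3 libraries. The rule fixed for unnamed models was to name, per comparison, the 2 with the highest and the 2 with the lowest fold change among called models with a mean of at least 1 CPM and no overlap between the 3 and 3 libraries. Since edgeR called no model, the 2 with the smallest p in each direction are named under the other conditions of that rule, and these were chosen after their values were seen. Measures of whole libraries were compared by exact two-sided permutation tests on the difference of means, which cannot give a p below 0.1 with 3 samples against 3. Between-library correlations used all 362880 orderings of the 9 libraries (Python 3.11.15, scipy 1.17.1).

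Planned before the data were examined were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM, DESeq2 1.42.0 (Wald test), limma 3.58.1 (voom), no filter, a minimum of 10 counts in every library of a group, fits on only the 6 libraries compared, the replicate number as a block, stricter thresholds, and leaving out each library in turn. Added after seeing the data were fits without the 2 most divergent libraries (edgeR and DESeq2), limma-voom with library quality weights, a robust edgeR fit, a fit with the rRNA and mitochondrial sequences, a fit without 5 models that moved in proportion, and a fit with the unassigned share as a covariate. The labels number the samples of each group 1 to 3 but do not say that equal numbers share a batch.

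The pipeline was tested on simulated negative binomial counts with the libraries' own sizes, means and dispersions. A single set was drawn per comparison, with each model drawn on its own. With 13258 models in the simulated morpholino comparison, edgeR recovered 2.08% of models changed 2-fold, 44.7% of those changed 4-fold, 80.0% of those changed 8-fold and 89.6% of those changed 16-fold, and 5.41% of its calls were unchanged models. With 13158 models in the simulated dnTCF comparison the recovered shares were 2.08%, 39.1%, 81.2% and 87.8%, and 0.98% of calls were unchanged models. DESeq2 recovered 72.3% and 60.9% of the 4-fold changes in these comparisons, and 19.9% and 22.4% of its calls were unchanged models.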

Results

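Gene expression was measured by poly-A RNA-seq in 9 samples of Nematostella vectensis embryos at 24 h after fertilization. The 3 groups were dextran-injected controls, embryos with a morpholino against BMP2/4, a secreted ligand of the bone morphogenetic protein family, and embryos with RNA for a dominant negative TCF (dnTCF), a form of the DNA-binding partner of β-catenin that blocks canonical Wnt (cWNT) transcription. Each group held 3 libraries. Counts on gene models ranged from 1936858 in dnTCF replicate 2 to 5994290 in dnTCF replicate 1, and 21946 models had at least 1 count in some library. Between 16002 and 18902 models were detected per library.

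The libraries differed widely in makeup, within groups as well as between them. In dextran replicate 3, 87.8% of 25507802 counts carried no reference sequence, which left 3101012 on gene models. The share was 58.9% in BMP2/4 morpholino replicate 1, 57.1% in dextran replicate 2 and 49.2% in dextran replicate 1, and it lay between 39.6% and 43.5% in the other 5 libraries. Group means were 64.7% ± 20.4 for dextran, 48.1% ± 9.35 for the morpholino (exact permutation p = 0.3, two-sided, n = 3) and 40.3% ± 0.739 for dnTCF (exact permutation p = 0.1, the smallest that 3 against 3 allows). BMP2/4 morpholino replicate 1 was the least similar library. Its correlation with the others on log2 CPM ran from 0.76 to 0.83, whereas the lowest value among the other 8 libraries was 0.84.

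**Figure D1:**
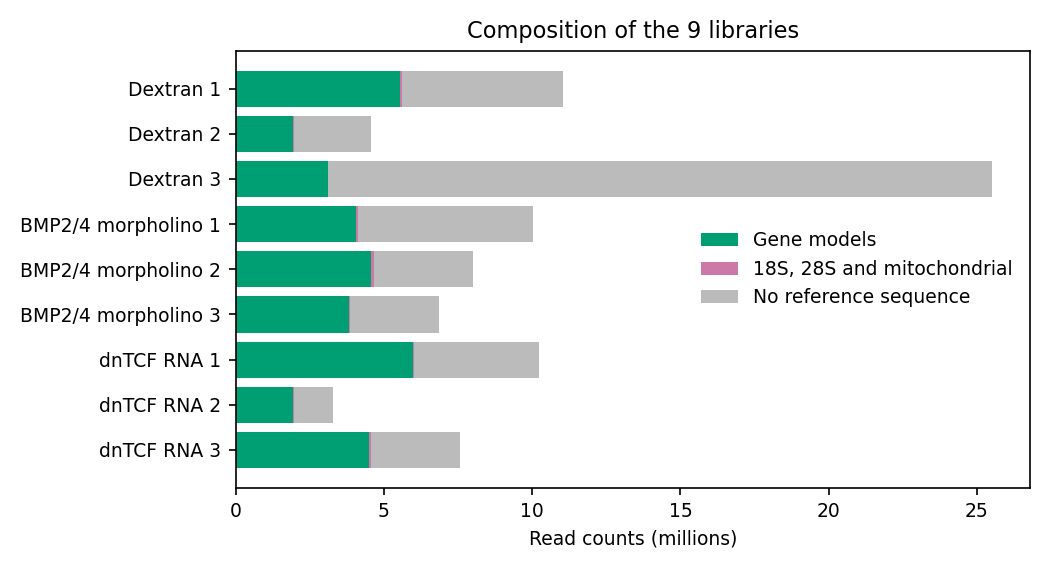
Read counts per library (horizontal axis, in units of 1e6), stacked as counts on gene models, counts on the 18S, 28S and mitochondrial sequences, and counts with no reference sequence. Dextran replicate 3 is the largest library, with 87.8% of its counts unassigned.

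**Figure D2:**
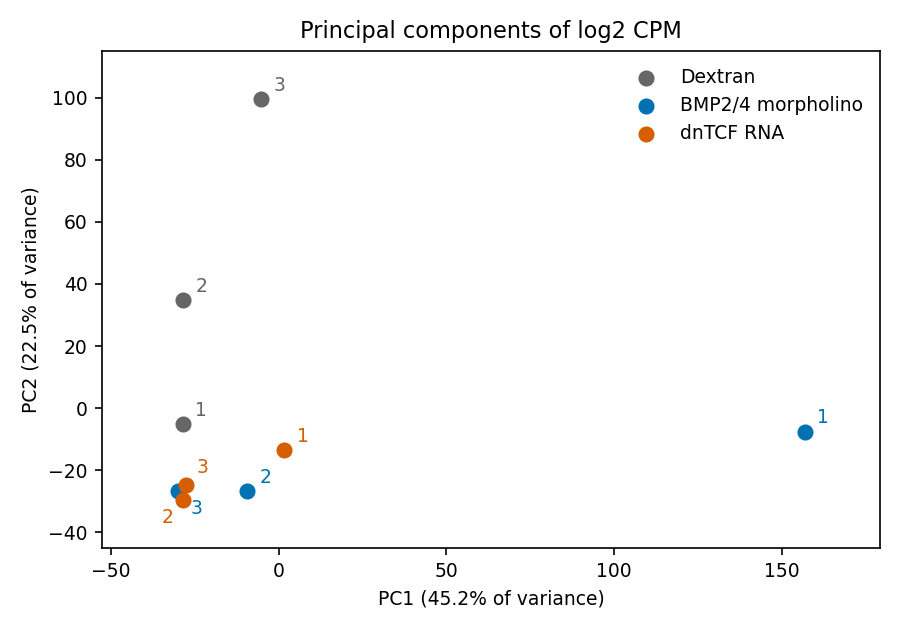
First and second principal components of log2 CPM over 13559 tested models; each point is 1 library, coloured by group and numbered by replicate. BMP2/4 morpholino replicate 1 sits alone on the first component (45.2% of variance) and dextran replicate 3 at the end of the second (22.5%).

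In these poly-A enriched libraries, the counts left on ribosomal RNA were higher with the morpholino than with dextran, without passing the test. How well rRNA was removed from each library was not measured. Counts on 28S rRNA were 8211 ± 2748 CPM (counts relative to those on gene models) with the morpholino, 6318 ± 1960 with dnTCF and 3549 ± 1213 with dextran (SD, n = 3 each). For 18S rRNA the values were 6049 ± 2658, 3188 ± 1289 and 1995 ± 942. All 3 morpholino libraries lay above all 3 dextran libraries for both rRNAs (exact permutation p = 0.1 each, two-sided, adjusted p = 0.2 over 10 tests). The dnTCF libraries overlapped the controls (exact permutation p = 0.2 each). Mitochondrial counts were 498, 278 and 60.4 CPM in the morpholino libraries, 24.3 to 41.1 with dnTCF and 8.72 to 75.6 with dextran. The morpholino mean was 5.83 times that of dextran, a difference that did not pass the test (exact permutation p = 0.2).

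A set of 5 gene models made up 52157 CPM in dextran replicate 3, and 5661 and 1644 in dextran replicates 2 and 1. The set was defined after the values were seen, as models with at least 1000 CPM in dextran replicate 3 and 50 times the median of the other libraries. Its level was 1582 in BMP2/4 morpholino replicate 1, 147 and 611 in the other morpholino libraries, and 53.1 to 101 with dnTCF. Across the 9 libraries the log10 level followed the unassigned share, with Pearson's r = 0.92 (exact permutation p = 0.0002039, adjusted p = 0.0008157 over 4 values) and Spearman's rho = 0.90 (exact permutation p = 0.002028, adjusted p = 0.002704). The models were chosen for their level in dextran replicate 3, which also has the highest share, so these p-values partly restate that choice. In the 8 libraries without it r was 0.89 (exact permutation p = 0.001835, adjusted p = 0.002704) and rho 0.86 (exact permutation p = 0.01071, adjusted p = 0.01071). Without dextran replicate 3 and BMP2/4 morpholino replicate 1, the 2 libraries farthest from the median share, r was 0.94. The order of level and share was also the same within the dextran and within the morpholino group, and not within dnTCF, whose libraries spanned few percentage points. Groups of 3 were too small for a value of their own. Levels were highest with dextran, and both levels and shares were lowest with dnTCF. The orderings ran over the libraries regardless of group. The p-values above therefore do not separate a relation between libraries from a difference between groups, and the 4 values are versions of 1 relation.

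**Figure D3:**
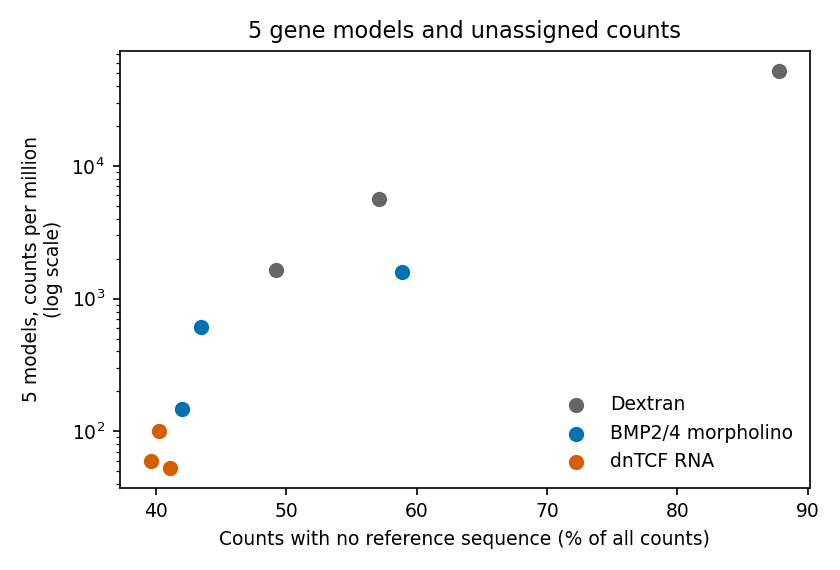
Summed level of 5 gene models in CPM relative to all gene-model counts (vertical axis, log scale) against the share of all counts with no reference sequence (horizontal axis, %); each point is 1 library, coloured by group. The level runs from 53.1 to 52157 and is highest where the unassigned share is highest, 87.8%.

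The comparison of the BMP2/4 morpholino with dextran asked which transcripts depend on BMP2/4 at this stage. The leading differences were large, but none of 13559 models passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (lowest adjusted p = 0.132). Model 194914 stood at 168 ± 29.3 CPM with the morpholino and 19.4 ± 10.7 CPM with dextran (SD, n = 3 each), 8.54-fold higher (log2 fold change 3.09, SE 0.403, edgeR adjusted p = 0.132). Model 93004 stood at 13.8 ± 1.89 against 1.10 ± 0.891 CPM, on 13, 1 and 2 counts in the dextran libraries (log2 fold change 3.42, SE 0.572, edgeR adjusted p = 0.197; 4.44 without dextran replicate 1). In the other direction, model 246365 stood at 10.5 ± 0.978 against 69.8 ± 27.5 CPM (log2 fold change -2.73, SE 0.379, edgeR adjusted p = 0.132), and model 183101 at 25.8 ± 10.5 against 211 ± 114 CPM (log2 fold change -3.03, SE 0.473, edgeR adjusted p = 0.197; -2.27 without both divergent libraries, BMP2/4 morpholino replicate 1 and dextran replicate 3). All 3 morpholino libraries lay on one side of all 3 dextran libraries for each of these 4 models, which was a condition of their choice.

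Over all tested models, the 4 named ones included, 1599 had an unadjusted edgeR p under 0.05, where 678 would do so by chance. That chance count is a mean, and models that move together can take a single grouping far from it. Setting BMP2/4 morpholino replicate 1 with dextran replicates 2 and 3 against the rest gave 1580. Of the 1599, 953 were higher and 646 lower with the morpholino. Scaling by library totals changed that balance, with 583 higher and 647 lower. The 3 and 3 libraries did not overlap for 14.8% of models, where chance gives 10%, and among those 483 were at least 2-fold higher and 557 at least 2-fold lower. Limma-voom also called 0 models, with 577 higher and 757 lower at an unadjusted p under 0.05, and DESeq2's Wald test called 116 higher and 112 lower, including all 4 models named here. Without dextran replicate 1, edgeR called 10 models, and without BMP2/4 morpholino replicate 1 and dextran replicate 3 together it called 5 higher and 15 lower. The count of models at an unadjusted p under 0.05 was 2623 without BMP2/4 morpholino replicate 3, 953 without dextran replicate 2, 1031 without dextran replicate 3 and 970 in a fit on only the 6 libraries compared (652 by chance).

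The comparison of dnTCF RNA with dextran asked the same of TCF-dependent transcription. Model 194914 again had the smallest p among models with higher values, at 117 ± 22 CPM with dnTCF against 19.4 ± 10.7 CPM with dextran (5.96-fold, log2 fold change 2.58, SE 0.395, edgeR adjusted p = 0.329). Model 212994 stood at 26.1 ± 2.85 against 2.03 ± 2.07 CPM, on 27, 2 and 2 counts in the dextran libraries (log2 fold change 3.48, SE 0.579, edgeR adjusted p = 0.335; 4.95 without dextran replicate 1 and 2.48 with the unassigned share as a covariate). Model 246365 stood at 13.0 ± 3.93 against 69.8 ± 27.5 CPM (log2 fold change -2.44, SE 0.375, edgeR adjusted p = 0.329) and model 208035 at 7 ± 2.34 against 45.9 ± 23.3 CPM (log2 fold change -2.71, SE 0.505, edgeR adjusted p = 0.335; -3.70 with the unassigned share as a covariate). The 3 dnTCF libraries did not overlap the dextran libraries for any of these 4 models, again a condition of their choice. No model was called by edgeR, and 662 had an unadjusted p under 0.05, where chance gives 678, 264 higher and 398 lower. A fit on only the 6 libraries compared also called 0, with 476 higher and 715 lower at that level, where chance gives 642 in all.

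The groups did not overlap for 14.4% of models, against 10% by chance, with 378 at least 2-fold higher and 461 at least 2-fold lower with dnTCF. Limma-voom called 0 models as well, with 284 higher and 407 lower at an unadjusted p under 0.05, and DESeq2 called 39 higher and 52 lower, again including the 4 named models. Without BMP2/4 morpholino replicate 1 edgeR called 1 higher and 2 lower, with 583 higher and 790 lower at an unadjusted p under 0.05. Without dextran replicate 1 it called 8 higher and 0 lower, and the balance at that level turned to 561 higher and 450 lower. Without both divergent libraries it called 6 higher and 36 lower. The unadjusted count was 437 without dnTCF replicate 3, 430 without dextran replicate 2, 1223 (478 higher, 745 lower) without both divergent libraries and 2175 (1046 higher, 1129 lower) by limma-voom with library quality weights.

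**Figure D4:**
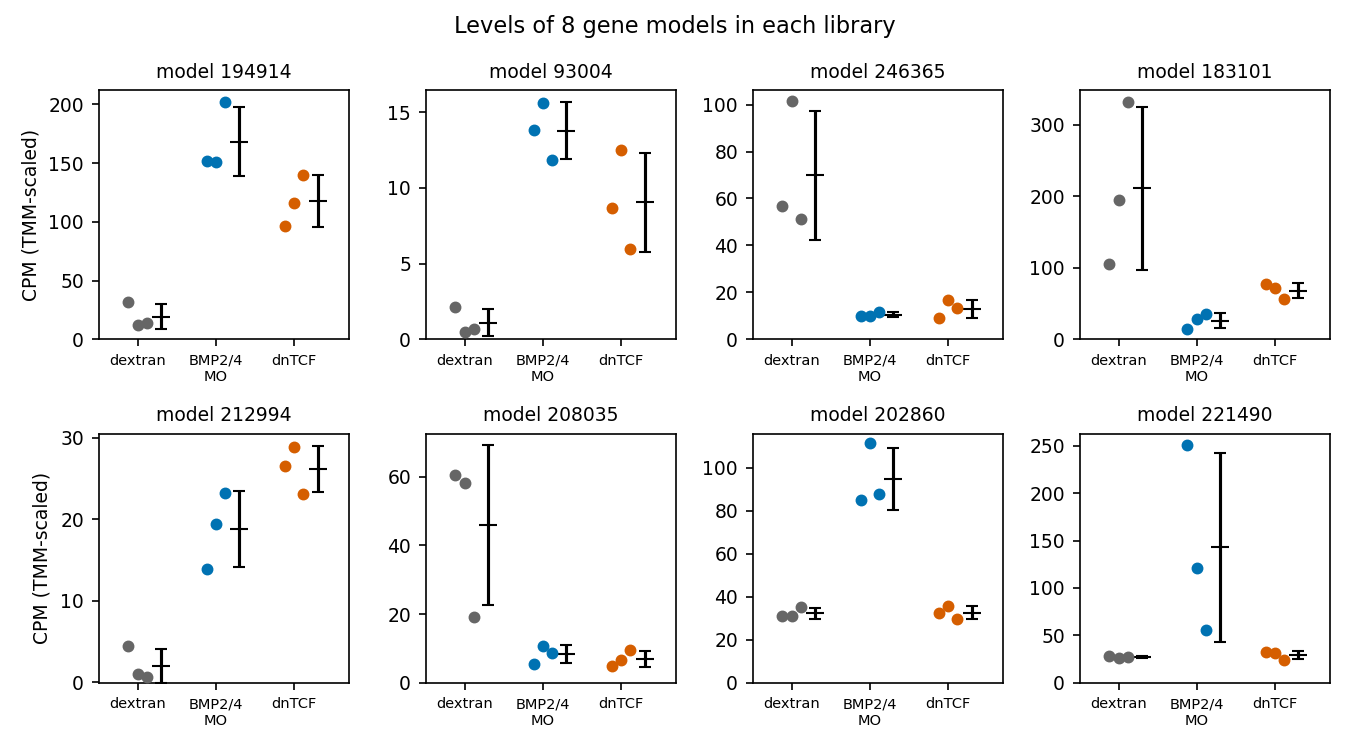
TMM-scaled CPM (vertical axes, scaled per panel) of 8 gene models in the dextran, BMP2/4 morpholino (MO) and dnTCF libraries; coloured points are single libraries, and black marks with bars are the mean ± SD (n = 3). Models 194914, 93004 and 212994 are higher and models 246365, 183101 and 208035 lower in both perturbed groups than in dextran, while models 202860 and 221490 are higher with the morpholino alone; none passed edgeR's adjusted threshold.

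The title of the series places BMP and cWNT signalling in opposition, so the direction of the changes in both comparisons was examined next. Across the 13559 models the 2 log2 fold changes against dextran correlated at Pearson's r = 0.67 and Spearman's rho = 0.61; this is across genes, which are not independent replicates, and the dextran libraries are common to both. Simulated unchanged groups that shared the controls gave a mean r of 0.50 (highest 0.53 in 50 draws). The observed covariance was 0.378 against 0.173 in the simulation, a difference of 0.205. The simulation draws each model on its own and so leaves out the joint movement of models within a library. A reference that keeps it, 512 sign patterns of the libraries' own deviations from their group means, gave a mean r of 0.42 with single patterns from -0.43 to 1 (the latter where the deviations of both perturbed groups cancel), against 0.66 for the observed differences of mean log2 CPM. The covariance of those differences was 0.340 against a mean of 0.133 (highest 0.486), and 20 of the 512 patterns reached it. Each group's deviations sum to 0, so in some patterns a whole group cancels. Where dextran cancels no control noise is shared, and where 1 perturbed group cancels with it r has no meaning. A pattern and its full reverse give the same covariance, so the patterns are not separate draws. Their share is not a p-value, and the mean r is only a rough reference. Among models with an unadjusted edgeR p under 0.05 in both comparisons, 144 were higher in both and 252 lower in both, and 0 went in opposite directions. Independent lists would share 18.6 and 19.0, and the simulation gave a mean of 136 in the same direction (highest 158) and 1.46 in opposite directions. The simulated lists were not matched in size to the real ones, which held 1599 and 662 models. The observed and simulated overlaps are therefore not directly comparable.

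Models 194914 and 246365 had the smallest p of their direction in both comparisons (4.86e-05 or less by edgeR, unadjusted), and in 4 of 50 simulated unchanged sets some model reached such a p in both, but in 0 of 50 did a model of each direction. Neither edgeR nor limma-voom called a model in both comparisons. Of DESeq2's calls, 28 were higher in both and 34 lower in both, where independent lists would share 0.336 and 0.432, and 0 were in opposite directions. DESeq2 runs on 10 simulated unchanged sets, which also leave out joint movement, gave at most 3 shared calls. In those sets, which hold no changed model, it still called a mean of 9.4 models (highest 16) for the morpholino. For dnTCF the mean was 8.9 (highest 15). With 3 dextran libraries the controls could not be split into groups of at least 2, so part of the excess may come from the shared controls. Both perturbed groups also received nucleic acid, which the dextran controls did not. A common response to it cannot be told apart from specific effects of the perturbations, so the shared direction does not bear on the opposition in the title.

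**Figure D5:**
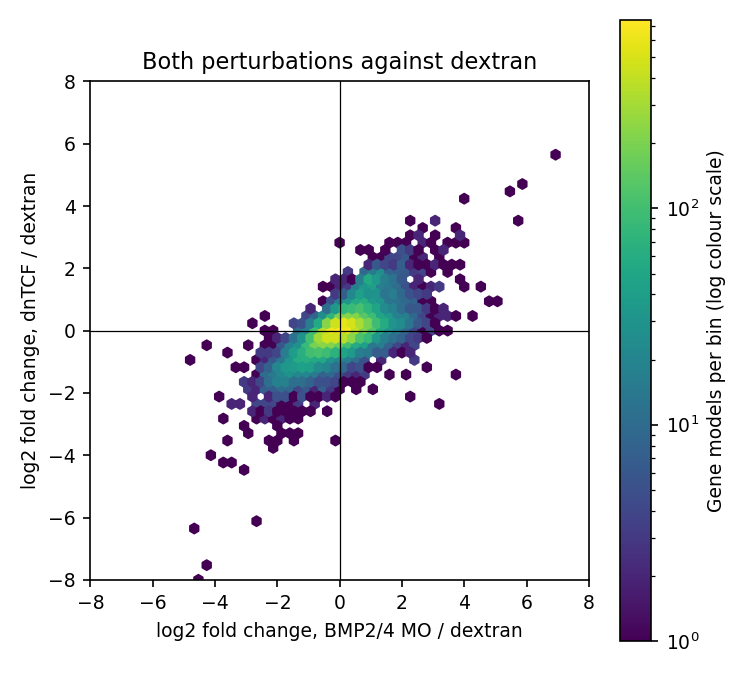
Log2 fold change of dnTCF over dextran (vertical axis) against that of the BMP2/4 morpholino over dextran (horizontal axis) for 13559 gene models, binned, with the number of models per bin as colour on a log scale; 6 models lie beyond ±8. The models lie along the rising diagonal (r = 0.67). Unchanged groups sharing the dextran libraries gave a mean r of 0.50 when simulated. Over 512 sign patterns of the libraries' own deviations the mean was 0.42, with single patterns from -0.43 to 1. In some of these patterns the dextran deviations cancel, so that no control noise is shared.

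The perturbations were also compared with each other, which tests the difference between their effects directly. Model 202860 stood at 94.7 ± 14.6 CPM with the morpholino and 32.6 ± 3.09 CPM with dnTCF, with the dextran libraries at 31, 30.8 and 35.3 CPM (log2 difference, dnTCF minus morpholino, -1.54, SE 0.265, edgeR adjusted p = 0.911). Model 221490 stood at 143 ± 99.3 CPM with the morpholino against 29.4 ± 4.36 CPM with dnTCF (log2 difference -2.28, SE 0.471, edgeR adjusted p = 0.911), with morpholino values of 251, 121 and 56.1 CPM and a log2 difference of -1.58 without BMP2/4 morpholino replicate 1. Model 1099 stood at 33.0 ± 13.2 CPM with dnTCF against 4.66 ± 1.69 CPM with the morpholino, and at 7.35, 5.96 and 1.36 CPM with dextran (log2 difference 2.81, SE 0.584, edgeR adjusted p = 0.911). Model 118347 had 0, 1 and 1 counts in the morpholino libraries, so no fold is given. Its mean was 2.77 ± 1.57 CPM with dnTCF, and the dextran libraries stood at 3.757, 5.965 and 1.699 CPM.

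No model was called by edgeR in this comparison, and 635 had an unadjusted p under 0.05 where chance gives 678, with 90 higher and 545 lower with dnTCF. The groups did not overlap for 9.48% of models, against 10% by chance, with 113 at least 2-fold higher and 279 at least 2-fold lower with dnTCF. Library totals in place of TMM gave 105 higher and 286 lower at an unadjusted p under 0.05. Limma-voom called 0 models and gave 135 and 244 at that level, and DESeq2 called 1 higher and 3 lower. The unadjusted count was 303 without dnTCF replicate 3, 339 without dnTCF replicate 2, 367 without dnTCF replicate 1, 969 without BMP2/4 morpholino replicate 2, 1637 without BMP2/4 morpholino replicate 3 and 374 in a fit on only the 6 libraries compared (658 by chance).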

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

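The test in this part was chosen after the result was seen. Counts on ribosomal RNA lay outside the gene-model comparisons and were above the control level in every morpholino library. The 28S sequence stood at 8211 ± 2748 CPM (relative to gene-model counts) with the BMP2/4 morpholino (5076 to 10203) against 3549 ± 1213 with dextran (2530 to 4891), and the 18S sequence had 6049 ± 2658 (3483 to 8791) against 1995 ± 942 (1237 to 3049). The exact permutation p of 0.1 for each is the smallest that 3 libraries against 3 can give. The libraries were enriched for poly-A mRNA, and how well rRNA was removed from each was not measured. Groups of 3 are too small for a test of single outlying samples, and edgeR's test of the difference between the perturbations gave 0 models, with 635 at an unadjusted p under 0.05, 4 calls by DESeq2 and 0 by limma-voom.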

How the results depend on the processing

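The fits without both divergent libraries, with library quality weights, with the robust estimate, with the rRNA and mitochondrial sequences, without the 5 proportional models and with the unassigned share as a covariate were chosen after seeing the data. The edgeR counts of 0 held for all comparisons under DESeq2 size factors, upper-quartile scaling, library totals, the filter of 10 counts, the fits on 6 libraries, limma-voom, both stricter thresholds and the replicate block, and under the last 4 of those added fits. For the morpholino against dextran, the count was 228 with DESeq2, 6 with no filter, 0 to 10 with 1 library left out (10 without dextran replicate 1), 20 without both divergent libraries (188 with DESeq2) and 91 with library quality weights. For dnTCF against dextran it was 91 with DESeq2, 18 with no filter, 0 to 8 with 1 library left out (8 without dextran replicate 1), 42 without both divergent libraries (203 with DESeq2) and 347 with quality weights. For dnTCF against the morpholino it was 4 with DESeq2, 0 with any 1 library left out, 21 with DESeq2 without both divergent libraries and 1 with quality weights. Models called in both comparisons in the same direction numbered 62 with DESeq2, 2 with no filter, 0 to 8 with 1 library left out, 13 and 104 (DESeq2) without both divergent libraries and 70 with quality weights; none was called in opposite directions under any of these. The correlation of the fold changes was 0.56 to 0.80 with 1 library left out, 0.80 with quality weights and 0.81 with the unassigned share as a covariate, against 0.67 and a spread of 0.0815 over the fits with 1 library left out. All 298 values of the 12 named results under the alternatives kept their direction, and 49 passed an adjusted p of 0.05. The named models were chosen for no overlap between the groups compared, so a kept direction was largely fixed by that choice. BMP2/4 morpholino replicate 1 is in neither group of dnTCF against dextran, and enters that comparison only through the shared spread, the filter and the scaling. Without it the models at an unadjusted p under 0.05 rose from 662 to 1373 there. The log2 fold change of model 194914 moved only from 2.58 to 2.54. The cause of the other differences between settings was not tested. With the replicate block the counts stayed at 0, 0 and 0, and 401 models had an unadjusted p under 0.05 between dnTCF and the morpholino; only 3 of 9 same-numbered pairs deviated together at r above 0.1 (lowest -0.22) and 2 of 9 libraries were closest to their own number, so the numbers were not taken as pairs. Leaving out a library leaves 2 in its group, whose spread is taken from all groups. The gene list tests and the sum over several models of 1 gene were not run, since the files give no gene names. In the simulated morpholino comparison edgeR recovered 2.08% of 2-fold changes (1 of 48) and 80.0% of 8-fold changes (40 of 50). That was a single draw with each model drawn on its own, and its planted changes ease the Benjamini-Hochberg adjustment. It sets no limit for the real libraries, where model 194914 was 8.54-fold higher with the morpholino at an edgeR adjusted p of 0.132.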

Other observations

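The tests of explanations and the splits in this part were chosen after the results were seen, while leaving out single libraries was planned.

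Models 202860 and 1099 were chosen for their small p in the direct comparison of the perturbations, in which edgeR called 0 models and 635 had an unadjusted p under 0.05 where chance gives 678 (969 without BMP2/4 morpholino replicate 2, 1637 without replicate 3 and 303 without dnTCF replicate 3), and their values alone do not show a class of models specific to 1 perturbation. Model 202860 was 1.55 log2 units above dextran with the morpholino (SE 0.265, edgeR adjusted p = 0.197) and 0.0056 above it with dnTCF (SE 0.262), and model 1099 was 2.73 above it with dnTCF (SE 0.587, edgeR adjusted p = 0.335) and -0.08 from it with the morpholino (SE 0.588). DESeq2, with 4 calls in that comparison, called both (adjusted p = 4.56e-05 and 0.013), and limma-voom called neither (adjusted p = 0.894 each); the adjusted p over all alternatives ran from 4.56e-05 to 1 and from 0.000146 to 1. On 10 simulated unchanged sets DESeq2 called up to 16 models for the morpholino and up to 15 for dnTCF against dextran. The direct comparison was not simulated, so its 4 calls have no reference of their own. Over all alternatives the log2 difference of model 202860 ran from -1.68 to -1.40 and that of model 1099 from 2.42 to 3.09.

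One pattern was the joint rise of 5 models in dextran replicate 3. Their summed level differed 983-fold between libraries while no model's share of the 5 differed by more than 2.052-fold (1.557-fold among the 6 libraries with at least 500 counts of the 5). The model with the widest range made up 35.8%, 18.4% and 34.9% of the 5 in dnTCF replicates 1 to 3 and 17.5% in dextran replicate 3. Whether a single sequence source feeds all 5 stays open, since the spread of shares that a single source would give between libraries was not measured. An effect of dextran injection stays open, since the dextran libraries held the 3 highest levels, but the lowest was only 1.039 times BMP2/4 morpholino replicate 1.

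Another pattern was the distance of BMP2/4 morpholino replicate 1 from every other library. Its highest correlation with any library was 0.8291, with dnTCF replicate 1, under the lowest among the other 8. Its group mates, BMP2/4 morpholino replicates 2 and 3, stood at 0.807 and 0.772. An exchange with a library of another group stays open, since a library far from all others cannot be placed in any group. BMP2/4 morpholino replicate 1 had more counts than 4 other libraries, which argues against low depth. At 26 models it had 0 counts where the median of the other libraries was above 20 CPM (median level elsewhere 37.2 CPM, or 151 counts at its depth), and it showed 15331 models at a common depth of 1936858 counts against 16002 to 17253 elsewhere. Independent loss of molecules as the whole cause would leave its lowest models at random in other groups. Of its 272 lowest, 89.0% were also below the group mates in dnTCF replicate 1 (48.0% of all models) and 76.5% in dextran replicate 3 (50.5%). These are the libraries whose deviations correlated positively with its own. The share was not computed for the others, and all models are not matched in level to the lowest. No conclusion on independent loss is drawn for BMP2/4 morpholino replicate 1. Whether it shares an axis of variation with other groups stays open: its deviations correlated at r = 0.3283 with those of dnTCF replicate 1 and 0.205 with dextran replicate 3, but at -0.11 and -0.28 with dnTCF replicates 2 and 3 and -0.16 and -0.12 with dextran replicates 1 and 2 (deviations within a group sum to 0, so not all 3 can be positive), and 2 other libraries, BMP2/4 morpholino replicate 2 and dnTCF replicate 3, reached 0.36; no biological explanation was tested.

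The last pattern was that models 194914 and 246365 led both comparisons with dextran. With any 1 dextran library left out the smallest absolute log2 fold change of either was 2.073. Both models were chosen for a small p and for no overlap with any of the dextran libraries. That value was therefore largely fixed by the choice, and no conclusion on a single control library is drawn from it. Of 50 simulated sets of unchanged groups that share the dextran libraries, 4 held a model with p values as small in both comparisons and 0 held 1 such model in each direction, which is the observed pattern; chance through the shared controls is left open, because the simulation leaves out the joint movement of models within a library. A response to injected nucleic acid of any kind, as opposed to dextran, cannot be told apart from 2 specific effects, because both perturbed groups received nucleic acid; the perturbations differed by at most 0.518 log2 units for these models (SE 0.369).

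With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the morpholino against dextran, 10 of 10 splits matched edgeR's 0 calls (highest other 0), and the real split was the 1 with the most models at an unadjusted p under 0.05, 1599 against 1580. By DESeq2 2 of the 10 splits reached the real 228 calls, the other with 344; both 1580 and 344 came from setting BMP2/4 morpholino replicate 1 with dextran replicates 2 and 3 against the rest, which are the 3 libraries of these 6 with the highest unassigned shares, 57.1% to 87.8%. For dnTCF against dextran, 10 of 10 splits gave 0 edgeR calls, the real split gave the most unadjusted models, 662 against 578 in the next (1 of 10), and also the most DESeq2 calls, 91 against 2 (1 of 10). For the 2 perturbations against each other, 10 of 10 splits gave 0 edgeR calls, 4 of 10 reached the real 635 unadjusted models and 5 of 10 the real 4 DESeq2 calls, with highest others of 1545 and 40. Those came from BMP2/4 morpholino replicates 1 and 2 with dnTCF replicate 1 against the rest, a structure of the samples that crosses the groups.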
